A study of Mus musculus with 16 samples.

How the data were processed

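The series holds 16 single-channel arrays of dendritic cells grown from C57BL/6 mouse bone marrow with GM-CSF. Lactobacillus acidophilus NCFM was added to the cells at 10 µg/ml for 4, 10 or 18 h, and control cells were taken at the same times. NCFM groups have 3 arrays each, the 4 h control 3, and the 10 and 18 h controls 2 each, numbered 1 and 2. The deposited table gives an intensity for each of 45101 probe sets, normalized between arrays by the authors. Its values are linear whole numbers from 42 to 31573. How the probe sets were summarized, corrected for background and normalized is not given in the sources used here. The number of arrays sets the precision, and the labels do not say whether the replicates are separate animals or cultures, so p-values measure only the spread between these samples.

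Intensities were taken to log2. Of the probe sets 34945 name 1 gene, 932 name several, 9160 are unlisted in the probe table, and 64 are controls. For each gene the probe set with the highest mean over the 16 arrays was kept, which gave 18193 genes, 9010 of them with several probe sets. Gene identifiers matched the reference gene table for 34754 of 34958 entries. As the deposited table names no genome build, that table (GRCm38.p6) was used only for names, chromosomes and gene spans.

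Each gene was fitted in limma 3.58.1 under R 4.3.3 with a mean per group over all 16 arrays (lmFit and eBayes, 10 residual degrees of freedom). Contrasts were NCFM against control at each time, the difference of that effect between times, and control between times. P-values are two-sided and adjusted by Benjamini and Hochberg over all genes, and a gene was called at adjusted p under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The fit was tried in 5 runs on simulated data, with 200 genes changed in each. It recovered 86.3% of changes of 1 log2 unit at 4 h, 82.4% at 10 h, 85.7% at 18 h and 71.3% in the 4 to 10 h difference. The false shares were 5.82%, 3.96%, 4.96% and 3.48%. The simulated noise was independent between genes and arrays, without a shared effect of the array number, and fewer genes changed than were called here. These shares therefore do not measure the errors in the real data.

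Named genes follow a rule fixed before the data were examined: the 15 largest rises and 10 largest falls at each time among called genes whose NCFM arrays all lie beyond all control arrays, the 6 largest in each direction for each difference between times, and the 5 largest for control cells, where none passed. Measured members of the gene lists may be named as well. The 28 pathway lists and 11 cell type lists were fixed at the same point, from textbook knowledge, and 667 of their 764 genes were measured, 5 of them through an older symbol. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a kind at a time, and with camera at an estimated correlation and fry as alternatives. Camera compares a list with all other genes, while fry tests it against no change. The ranges of adjusted p given for a list over its alternatives include fry. The camera tests of differences between times were added after the data were seen, and were repeated with each array left out in turn.

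Whether array numbers pair the samples was checked from the data, since the labels give numbers only. Deviations from the group means correlated across genes in all 36 same-number pairs (0.19 to 0.75, median 0.42). The 70 pairs with different numbers lay between -0.75 and 0.73. In the 10 and 18 h controls the 2 deviations mirror each other, so their pairs are not separate evidence. Control 18 h replicate 2 had 0.73 with control 4 h replicate 3 and 0.40 with control 4 h replicate 2. Same-number arrays thus deviate alike, but number 2 of these controls is not shown to pair with number 2 elsewhere. The main fit has no block, so differences between array numbers add to its spread. Number 1 arrays also make up a larger share of the 10 and 18 h controls than of the NCFM groups. The fit with the number as a block was an alternative, and it takes equal numbers as paired in every group. Other alternatives fixed before the data were examined were quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, dim genes left out, an intensity trend with robust variance, array weights, a pseudocount of 16, only the groups compared, an adjusted p under 0.01, a minimum change of 1 log2 unit, and each array left out in turn. Added later were only arrays 2 and 3, only arrays 1 and 2 with the block, subtraction of each array's percentile 5 of intensity, and centring on the spike-in probe sets. No group has more than 3 arrays, so no test for outlying samples was made. Probe sets that name no single gene were left out of the comparisons.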

Results

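Dendritic cells were grown from mouse bone marrow with GM-CSF, and Lactobacillus acidophilus NCFM, a strain of a gut bacterium sold as a probiotic, was added to the immature cells for 4, 10 or 18 h. Messenger RNA was measured on 16 single-channel arrays in 6 groups. NCFM cells had 3 arrays at each time, and control cells had 3 arrays at 4 h, 2 at 10 h and 2 at 18 h. The median intensity of an array lay between 162 and 167, and the number of arrays limits the precision. Changes are given as log2 of the NCFM to control ratio with the standard error (SE) of the fit. Genes were compared within each time, so that n is 3 against 3 at 4 h and 3 against 2 at 10 and 18 h.

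The arrays separated by treatment first. The first principal component held 57.6% of the variance, with the 9 NCFM arrays between -44.4 and -5.50 and the 7 control arrays between 28.3 and 43.3. In all 6 groups the array numbered 1 also stood apart from its partners. Xist, the transcript of the inactive X chromosome, was lower on them (mean difference -4.32 on the log2 scale), and the Y-linked gene Eif2s3y was higher, at 9.81 to 10.3 against 5.98 to 6.19, near the 5th percentile of the arrays, on the others. On these arrays the cell cycle list lay 1.00 higher (mean of the 6 group differences of the list median), the dendritic cell markers 0.42 higher, and the macrophage markers differed by -0.50. Other lists lay to the same side in all 6 groups too. Interferon-inducible GTPases differed by -0.53, the inflammasome list by -0.47, antiviral effectors by -0.33, nitric oxide and prostanoid enzymes by -0.32 and oxidative phosphorylation by 0.26. Number 1 arrays are a larger share of the 10 and 18 h controls than of the NCFM groups, so such differences enter those comparisons. NCFM 4 h replicate 3 had 321 brighter genes at least 2-fold lower than on its partners. On it the oxidative phosphorylation list had a median difference of -0.69 and the ribosomal protein list of -0.65.

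**Figure D1:**
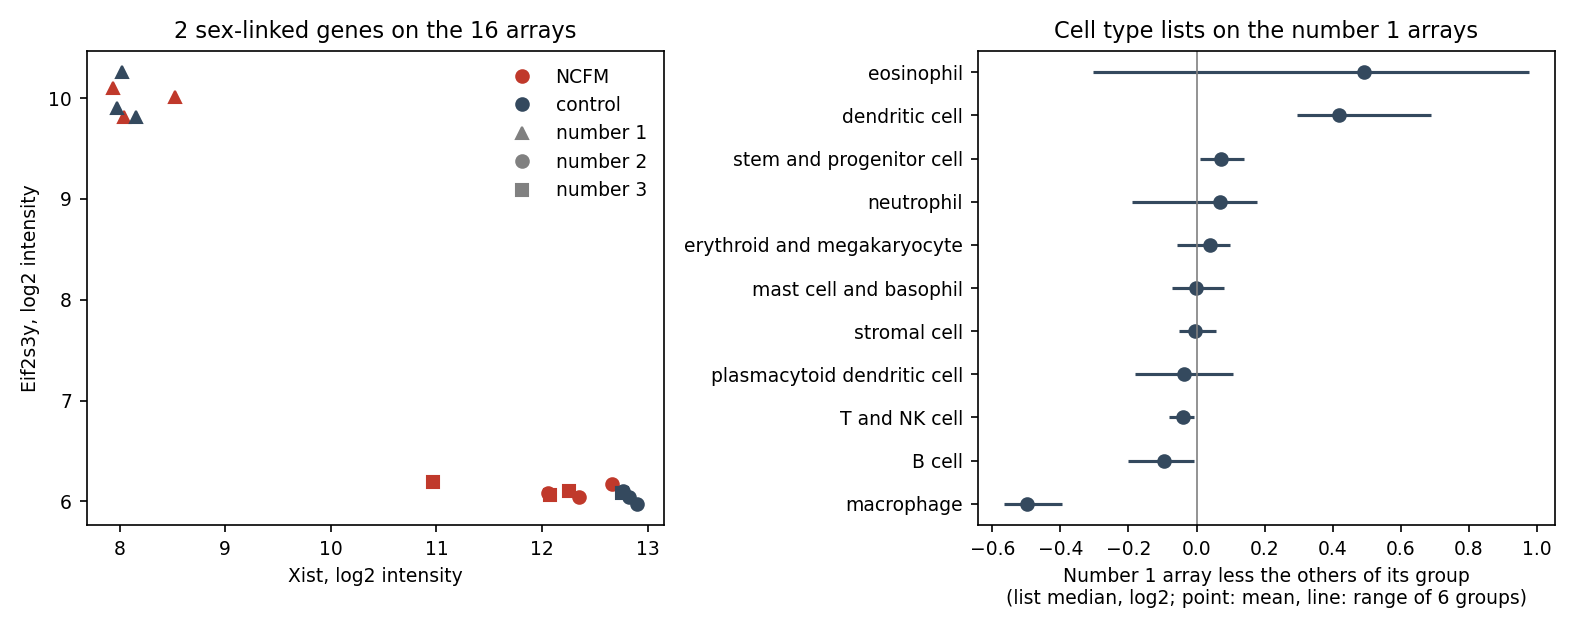
Left, Xist against Eif2s3y (log2 intensity) on each of the 16 arrays, where the 6 number 1 arrays have the lower Xist and the higher Eif2s3y; right, the difference of the number 1 array from the others of its group for the 11 cell type lists (list median, log2; point, mean; line, range of 6 groups). Macrophage markers lay lower (mean -0.50) and dendritic cell markers higher (mean 0.42) in all 6 groups.

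Which genes NCFM changes early was asked at 4 h. The gene with the largest rise was Ptgs2, the inducible cyclooxygenase that makes prostaglandins, which was 79.2-fold higher (6.31 ± 0.28 SE, n = 3 against 3, adjusted p = 1.37e-07). The control arrays had intensities of 80 to 107 for Ptgs2, near their first quartile of 105, so the fold depends on the background, and the rise was 8.21 with background subtracted. The inflammatory cytokine Il6 rose 58.1-fold (5.86 ± 0.32), Il12b, a subunit of interleukins 12 and 23, 35.6-fold (5.15 ± 0.35) and Tnf 24.5-fold (4.62 ± 0.18). The chemokines Cxcl9 (5.55 ± 0.40) and Cxcl10 (5.29 ± 0.44), which draw T cells, and Ccl4 (4.58 ± 0.21) rose with them. The interferon-induced genes Ifit2 (5.44 ± 0.62), Ifit1 (5.39 ± 0.57), Ifit1bl1 (5.16 ± 0.51), Cmpk2 (4.91 ± 0.33), Ifit3 (4.77 ± 0.59) and Rsad2 (4.56 ± 0.66) rose between 23.6- and 43.5-fold. The activation marker Cd69 rose by 4.61 ± 0.24 and Ch25h, which makes 25-hydroxycholesterol, by 4.58 ± 0.29. The largest falls were smaller. Cd300lb, a myeloid surface receptor, was 7.54-fold lower (-2.91 ± 0.34, adjusted p = 1.19e-04), followed by Arrdc3 (-2.76 ± 0.58), Zfp36l2 (-2.53 ± 0.19) and the chemokine receptor Cxcr4 (-2.37 ± 0.38). AI467606, Vsir, P2ry6, Ptger2, Sbk1 and Tmem154 lay between -2.18 and -2.07.

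In the limma fit 3335 of 18193 genes passed at 4 h, 959 higher and 2376 lower (71.2% lower). On 3302 of them every NCFM array lay beyond every control array. Over all genes 36.5% were separated in this way, where chance gives 10%. This chance value, and those at 10 and 18 h, take the arrays as exchangeable, without the shared effect of their number. With the replicate number as a block 4880, 5666 and 5557 genes passed at 4, 10 and 18 h. At least 2-fold changes numbered 371 rises and 211 falls, and 49 genes rose at least 8-fold. The split depends on the scaling: after quantile normalization 58.1% of the calls were lower, and after centring on the spike-in probe sets, after which the median change of all genes was 0.18, 17.8% were (3374 higher and 730 lower). The count was 2138 without control 4 h replicate 2 and 2207 without control 4 h replicate 3.

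**Figure D2:**
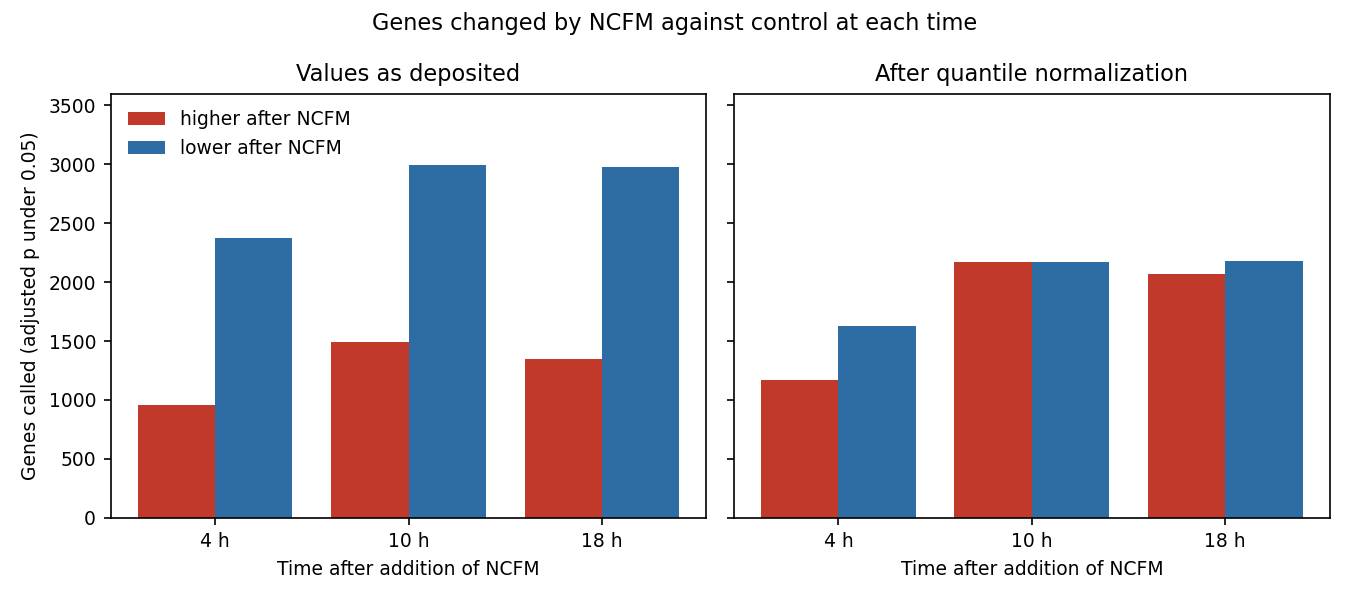
Number of genes called at adjusted p under 0.05 against control at 4, 10 and 18 h, higher and lower, with the deposited scaling and after quantile normalization (bars start at 0). Falls outnumbered rises with the deposited scaling (2376, 2995 and 2973 falls), and after quantile normalization the counts at 10 h were 2169 and 2169.

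Antiviral lists had the largest median changes at 4 h. With an estimated correlation the cytokine, chemokine, maturation and MHC class I lists had lower adjusted p. Of 38 measured interferon-stimulated antiviral effectors 36 rose (median 2.10; adjusted p = 8.9e-39), among them Oasl1 (3.73), Usp18 (3.59) and Mx1 (2.65). All 9 interferon-inducible GTPases rose (median 3.06; adjusted p = 9.91e-14), led by Iigp1 (4.07). Of 10 interferon ligands 1 passed, Ifnb1, the gene of interferon beta, at 3.43 ± 0.23, and the list was called (adjusted p = 0.0154, and 0.0843 with an estimated correlation). Among nucleic acid sensors 7 of 16 rose, with Ifih1 at 3.37 and Tlr3 at 1.97, and Mavs fell (-0.61; list adjusted p = 1.23e-05, and 0.116 with an estimated correlation). IRF and STAT factors had 5 rises, including Irf7 (3.34), and 1 fall, Irf3 (-0.46), among 14 (adjusted p = 2.92e-04, and 0.0843 with an estimated correlation). The antiviral effector and GTPase calls held with an estimated correlation (adjusted p = 0.0255 and 0.0396). Adjusted over the list alone, 36 effectors, 9 GTPases, 1 ligand and 5 IRF and STAT factors rose, and 8 sensors rose. Mavs lost its call without any array of NCFM 4 h or without control 4 h replicate 2 or 3, and its adjusted p ranged from 7.56e-04 to 0.114 over the alternatives.

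Inflammatory and maturation genes rose as well at 4 h. Of 27 cytokines 16 rose and of 28 chemokines 12, among them Il1a (4.19), Il1b (3.87) and Ccl3 (4.46) (adjusted p = 8.17e-15 and 8.31e-11). The maturation list had 13 rises among 24, with the co-stimulatory genes Cd40 at 3.92 ± 0.18 and Cd86 at 1.38 ± 0.21, while the migration receptor Ccr7 had 0.28 ± 0.37 and did not pass (list adjusted p = 2.46e-14). NF-kB targets and feedback genes had 17 rises of 21, led by Nfkbiz (3.89), and MHC class I presentation 9 of 15, including the peptide transporter Tap1 (1.96) (adjusted p = 6.82e-16 and 1.34e-08). Apoptosis genes had 5 rises of 17, with Mlkl at 1.57, and 1 fall, Bbc3 (adjusted p = 0.00185). These 6 lists passed with an estimated correlation at adjusted p = 0.0124 (cytokines), 0.017 (chemokines), 0.0208 (maturation), 0.0336 (NF-kB), 0.0208 (MHC class I) and 0.0416 (apoptosis). When adjusted over the list alone, 20, 14, 16, 19, 9 and 7 of their members rose, in the order cytokines, chemokines, maturation, NF-kB, MHC class I and apoptosis.

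A further set of lists passed at 4 h with the preset correlation only. SOCS and phosphatase feedback genes had 8 rises of 21, led by Socs3 (3.49), and 3 falls (adjusted p = 4.95e-05, and 0.106 with an estimated correlation). Nitric oxide, prostanoid and redox enzymes had 6 rises of 22, including Acod1 (2.60) (9.32e-07, and adjusted p = 0.119 estimated), and the inflammasome list 5 of 13, including Casp4 (2.26) (0.00365, and adjusted p = 0.382 estimated). Immediate early genes had 8 rises of 21 and 1 fall, Klf4 (-1.99) (0.015, and adjusted p = 0.382 estimated). Surface pattern receptors and adaptors had 5 rises of 22, including Nod1 (1.59), and 1 fall, Tlr4 (-0.67); Tlr2, the receptor that the series title names, had 0.69 ± 0.32 and did not pass (adjusted p = 0.168; list 0.0215, and 0.465 estimated). With the replicate number as a block Tlr2 passed (adjusted p = 0.031, over a range of 0.00692 to 0.485). Oxidative phosphorylation had 5 falls of 30, Atp5c1, Ndufb10, Ndufs3, Sdhb and Sdhd (median -0.54, adjusted p = 1.64e-04, and 0.382 estimated), no ribosomal protein gene of 18 passed (median -0.35, list 0.0138, and 0.605 estimated), and glycolysis had 1 rise, Slc2a6, and 1 fall, Pfkfb4, of 23 (0.0312, and 0.568 estimated). Adjusted over the list alone, rises numbered 9, 12, 5, 9 and 5 for the feedback, enzyme, inflammasome, immediate early and surface receptor lists, and oxidative phosphorylation had 8 falls. Without NCFM 4 h replicate 3 the oxidative phosphorylation median was -0.24, still called (adjusted p = 0.00388), and the calls of the ribosomal (0.21), glycolysis (0.132) and surface receptor (0.0834) lists were lost. The glycolysis call was also lost without NCFM 4 h replicate 2 (0.0652) or control 4 h replicate 3 (0.0717), and the surface receptor call without control 4 h replicate 1 (0.106); over all alternatives the adjusted p ranged up to 0.605 (ribosomal), 0.568 (glycolysis) and 0.465 (surface receptors). Single genes here rest on single arrays too: Tlr4 and Atp5c1 lost their calls without control 4 h replicate 2 or NCFM 4 h replicate 2, Ndufs3 without control 4 h replicate 2, and Ndufb10, Sdhd and Pfkfb4 without any of 8, 10 and 9 arrays (adjusted p up to 0.117, 0.128 and 0.169).

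At 10 h, where the question was which changes hold or begin as stimulation goes on, the same kinds of genes led. Ptgs2 was 57.5-fold higher (5.85 ± 0.31, n = 3 against 2, adjusted p = 8.92e-07), and Il6 34.3-fold (5.10 ± 0.36) and Il12b 32.8-fold (5.04 ± 0.39). Ifit1bl1 (5.76 ± 0.57), Ifit2 (5.31 ± 0.69), Cmpk2 (5.05 ± 0.37), Ifit3 (4.83 ± 0.65), Ifit1 (4.73 ± 0.64), Rsad2 (4.68 ± 0.74), the RNA exonuclease Isg20 (4.73 ± 0.30), the GTPase Iigp1 (4.73 ± 0.34) and Ms4a4c (4.66 ± 0.34) rose. So did Cxcl10 (5.34 ± 0.49), Cxcl11 (4.94 ± 0.19) and Cxcl9 (4.91 ± 0.45), the ligands of Cxcr3. The monocyte chemokine receptor Ccr2 was 8.17-fold lower (-3.03 ± 0.36, adjusted p = 1.03e-04), the mannose receptor Mrc1 6.16-fold lower (-2.62 ± 0.18), the lectin Clec10a 5.77-fold lower (-2.53 ± 0.35) and the transferrin receptor Tfrc 5.48-fold lower (-2.45 ± 0.20). Cd300lb (-2.90 ± 0.38), Tmem154 (-2.79 ± 0.38), Gcsh (-2.65 ± 0.22) and Amz1 (-2.58 ± 0.17) fell. Asgr2 (-3.17 ± 0.90) and Nrep (-2.41 ± 0.70) also passed, at adjusted p = 0.0227 and 0.0253, but without control 10 h replicate 1 they had -1.80 and -1.58 at adjusted p = 0.299 and 0.279, the highest over their alternatives, and neither passed without NCFM 10 h replicate 2 (0.068 and 0.0633) or NCFM 10 h replicate 3 (0.074 and 0.0816); the lowest over the alternatives were 0.00112 and 5.23e-05.

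At 10 h 4488 genes passed, 1493 higher and 2995 lower (66.7% lower). NCFM and control arrays were fully separated on 4477 of them, and over all genes on 52.1%, where chance gives 20%. At least 2-fold changes numbered 477 rises and 650 falls, with 59 rises and 2 falls (Asgr2 and Ccr2) of at least 8-fold. After quantile normalization 50% of the calls were lower (2169 of 4338), and 90.2% after spike-in centring, after which the median change of all genes was -0.24. The count was 2134 without control 10 h replicate 1, which leaves a single control array that is assumed to vary like the other groups.

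Antiviral lists were again called at 10 h. Of 38 effectors 37 rose (median 2.16), as did 9 of 9 GTPases (median 2.66), with adjusted p = 3.66e-29 and 2.35e-10, and 0.0579 and 0.0935 with an estimated correlation. Irf7 had 3.90, and IRF and STAT factors had 6 rises and 1 fall of 14 (0.0114, and adjusted p = 0.223 estimated). That call was lost without control 10 h replicate 2 (adjusted p = 0.0765, where the alternatives reached up to 0.223). Sensors had 7 rises and 2 falls, Mavs and Sting1, of 16 (0.00298, and adjusted p = 0.311 estimated). Ifnb1 had 1.30 ± 0.25 and Ifna4 0.27, the 2 rises among 10 interferon ligands, whose list was not called (adjusted p = 0.0663). Camera called this list without NCFM 10 h replicate 2 (0.0304) and without control 10 h replicate 2, which leaves 1 control array. Its adjusted p ranged from 0.00466 to 0.209 over the alternatives, among them fry. Control arrays lay at 100 to 113 for Ifna4, near their first quartile, and its change was 0.60 with background subtracted. It did not pass with the replicate number as a block (0.24, adjusted p = 0.0554, over a range of 0.0241 to 0.858), nor without NCFM 10 h replicate 3 or control 10 h replicate 1, and without the latter Mavs did not pass either (0.243, over a range of 0.00321 to 0.243). Cytokines had 16 rises of 27, including Il10 (3.05 ± 0.35, and 4.32 with background subtracted, since its control arrays lay at 101 to 114, near their first quartile), and 2 falls, and chemokines 14 of 28 (1.84e-08 and 1.31e-07, both 0.0417 with an estimated correlation). MHC class I presentation had 12 rises of 15, including the immunoproteasome gene Psmb9 (1.45) (6.52e-12, and 0.0202 estimated). Maturation genes had 14 rises of 24, with Cd40 at 4.37 and Cd86 at 2.03 (4.71e-10, and adjusted p = 0.0579 estimated). When adjusted over the list alone, 37 effectors, 9 GTPases, 6 IRF and STAT factors, 7 sensors, 3 ligands, 16 cytokines, 14 chemokines, 14 class I genes and 14 maturation genes rose.

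Cholesterol synthesis, oxidative phosphorylation and ribosomal protein lists fell at 10 h, each with the preset correlation only. Of 20 cholesterol synthesis genes 15 fell and none rose (median -0.997, adjusted p = 5.42e-08, and 0.127 with an estimated correlation), among them Sqle (-1.56 ± 0.28), Dhcr7 (-1.52 ± 0.17), Hmgcs1 (-0.87 ± 0.21) and the regulator Srebf2 (-1.07 ± 0.16). A second probe set of Fdft1 in this list went the other way (0.25 against -0.97). Oxidative phosphorylation had 13 falls of 30, including Ndufb10 (-1.23) (median -0.59; 4.03e-05, and adjusted p = 0.328 estimated). Ribosomal proteins had 6 falls of 18, including Rps6 (-0.95) (median -0.49; 0.00178, and adjusted p = 0.498 estimated). The cell cycle and DNA replication list, on which the number 1 arrays lie 1.00 higher, had a median of -0.97 but only 2 members passed, Cdk2 and Gmnn (list adjusted p = 0.0084, and 0.82 estimated). Without control 10 h replicate 1 the list lost its call, with a mean of -0.12 and a rank above the other genes. That fit sets NCFM arrays of all numbers against 1 control array, numbered 2. The number difference of this list then enters the comparison, so that fit cannot tell whether the fall holds. With the replicate number as a block, which takes up this difference, the list kept its call and direction. Without control 10 h replicate 1 the calls of Cdk2 (0.198), Gmnn (0.34), Rps6 (0.0738) and Ndufb10 were lost as well, where the adjusted p of Ndufb10 ranged from 2.63e-04 to 0.175, and Hmgcs1 was lost without control 10 h replicate 2 (0.0687, the highest of its alternatives). Also called were NF-kB targets (13 rises of 21; 5.36e-09, and adjusted p = 0.127 estimated), feedback genes (8 rises and 2 falls of 21; 0.00178, and adjusted p = 0.223), the nitric oxide and prostanoid enzymes (10 rises of 22, including Nos2 at 3.37; 5.24e-06, and adjusted p = 0.204) and the inflammasome list (6 rises and 1 fall of 13; 0.00298, and adjusted p = 0.328). Adjusted over the list alone, 16 cholesterol, 15 oxidative phosphorylation and 7 ribosomal genes fell, no cell cycle gene passed, and 15 NF-kB, 10 feedback, 11 enzyme and 6 inflammasome genes rose.

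**Figure D3:**
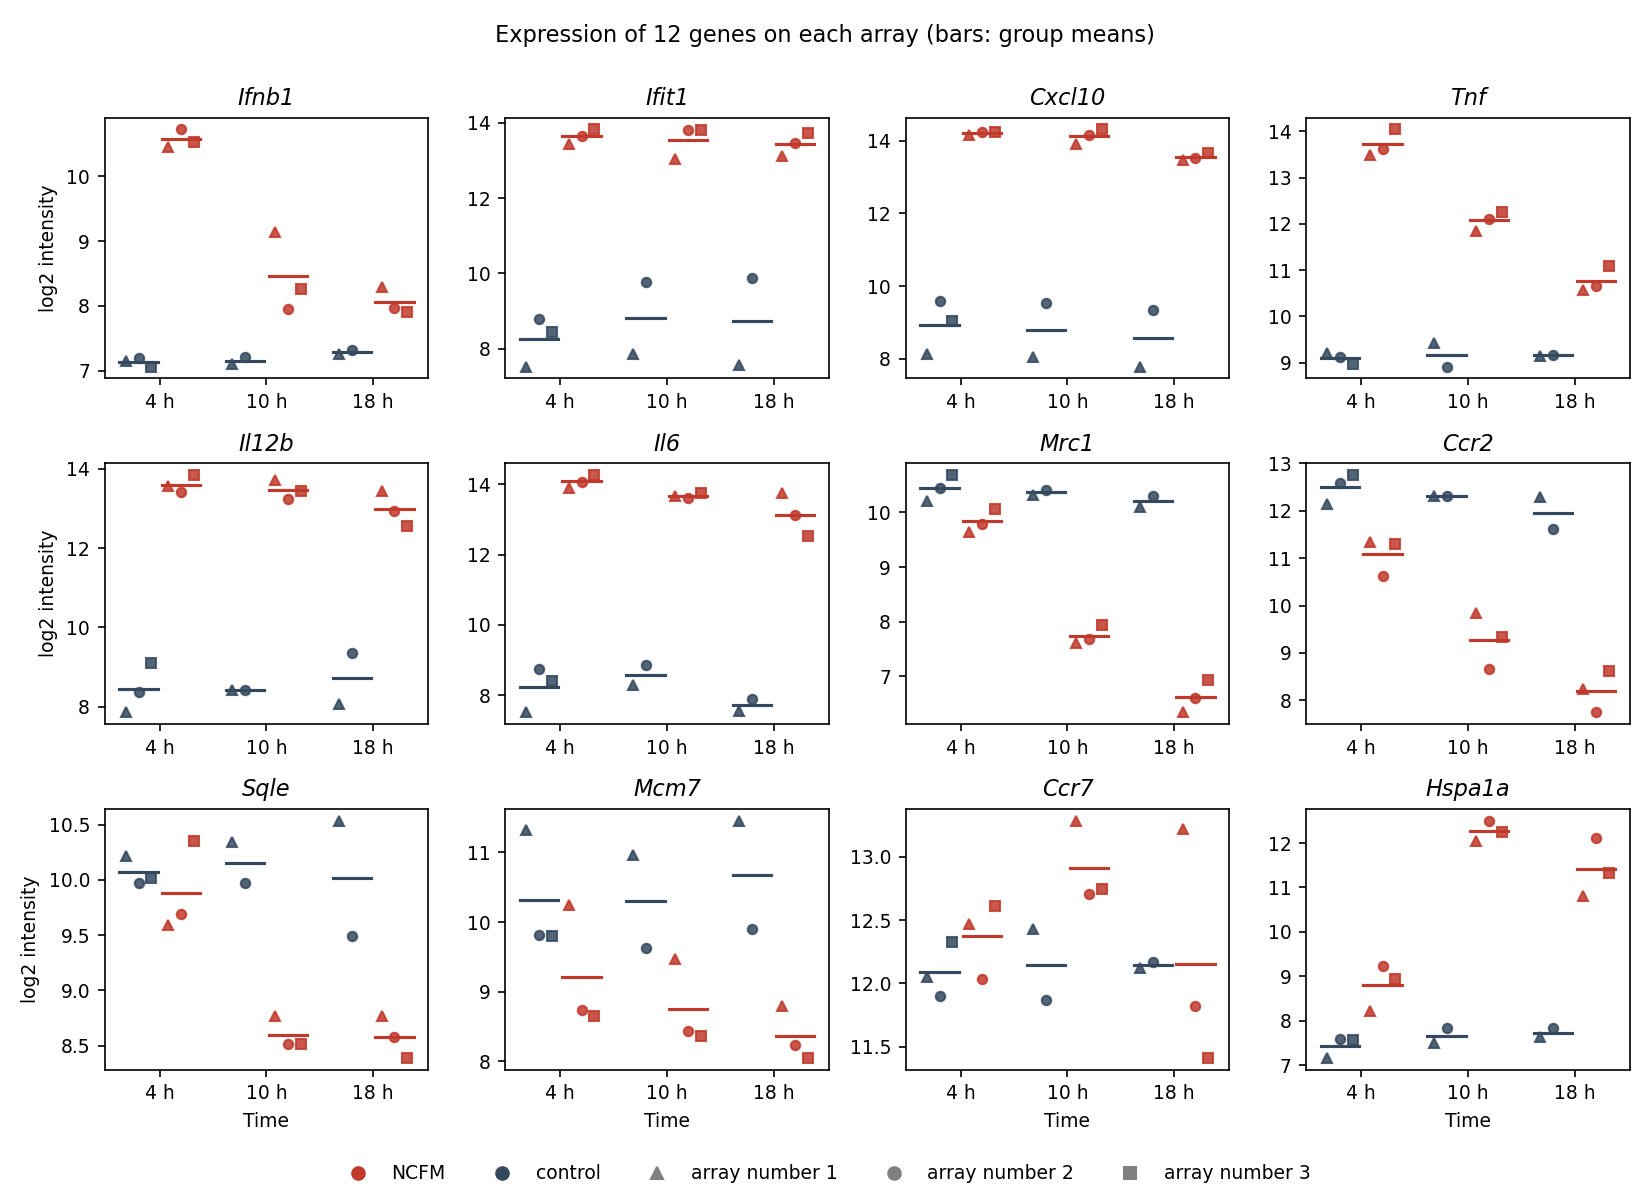
Log2 intensity of 12 genes on each array at 4, 10 and 18 h, NCFM and control (points, arrays; bars, group means). Mrc1 lay at 9.64 to 10.1 on the NCFM arrays at 4 h and at 6.34 to 6.93 at 18 h, while its control arrays lay between 10.1 and 10.7.

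At 18 h, the last time, Ptgs2 was 70.9-fold higher (6.15 ± 0.31, n = 3 against 2, adjusted p = 7.13e-07) and Il6 42.9-fold (5.42 ± 0.36). Ifit1bl1 (5.23 ± 0.57), Ifit2 (4.94 ± 0.69), Isg20 (4.80 ± 0.30), Cmpk2 (4.73 ± 0.37), Ifit1 (4.71 ± 0.64), Ms4a4c (4.67 ± 0.34), Slfn4 (4.51 ± 0.29), Rsad2 (4.47 ± 0.74), Iigp1 (4.41 ± 0.34) and Ifit3 (4.38 ± 0.65) rose between 20.8- and 37.5-fold. Cxcl10 (5.00 ± 0.49), Cxcl11 (4.74 ± 0.19) and Cxcl9 (4.56 ± 0.45) rose too. Ccr2 was 13.5-fold lower (-3.75 ± 0.36, adjusted p = 2.63e-05) and Mrc1 fell as well (-3.58 ± 0.18). Mrc1 had intensities of 81 to 122 on the NCFM 18 h arrays, near their first quartile of 107 to 108, so the size of its fall depends on the background and was -5.22 with background subtracted. In control cells Ptgs2 had 86 to 90 at 18 h, and with background subtracted its rise was 8.11. The lectin receptor Clec4a2 (-2.68 ± 0.20), Adgre4 (-3.05 ± 0.53), Ap1s2 (-2.74 ± 0.28), Cd300lb (-2.78 ± 0.38) and Gcsh (-2.54 ± 0.22) fell. Stmn1, a tubulin-binding protein of dividing cells (-3.10 ± 0.88), Asgr2 (-2.70 ± 0.90) and S100a4 (-2.61 ± 0.64) passed with adjusted p = 0.0233, 0.0478 and 0.0107. Without control 18 h replicate 1 they had -1.88, -1.46 and -2.55 at adjusted p = 0.212, 0.348 and 0.0518, and over their alternatives adjusted p ranged from 3.45e-05 to 0.212, 0.00327 to 0.348 and 5.44e-04 to 0.0529. Stmn1 and Asgr2 also lost their calls without NCFM 18 h replicate 2 (0.0692 and 0.119) or NCFM 18 h replicate 3 (0.0668 and 0.0979), S100a4 without control 18 h replicate 2 (0.0529), and Asgr2 without any of 7 further arrays (NCFM 18 h replicate 1, the 3 arrays of control 4 h, NCFM 4 h replicate 2 and NCFM 10 h replicates 2 and 3), when its adjusted p lay between 0.0561 and 0.068.

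At 18 h 4320 genes passed, 1347 higher and 2973 lower (68.8% lower). NCFM and control arrays were fully separated on 4304 of them, and over all genes on 47.2%, where chance gives 20%. At least 2-fold changes numbered 393 rises and 704 falls, with 47 rises and 4 falls (Ccr2, Mrc1, Stmn1 and Adgre4) of at least 8-fold. After quantile normalization 51.3% of the calls were lower (2181 of 4253), and 71.5% after spike-in centring. The count was 2868 without control 18 h replicate 2.

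At 18 h the antiviral effectors had 34 rises of 38 (median 1.67, adjusted p = 3e-25, and 0.106 with an estimated correlation) and all 9 GTPases rose (median 2.23; 8.15e-10, and adjusted p = 0.121 estimated). Ifnb1 had 0.77 ± 0.25 and was the 1 rise among 10 ligands, whose list was not called (0.237). Sensors had 8 rises and 1 fall of 16, with Tlr3 at 1.75 (0.012, and adjusted p = 0.374 estimated), and IRF and STAT factors 4 rises, including Irf7 (3.82), and 1 fall of 14 (0.0218, and adjusted p = 0.339 estimated). MHC class I genes had 12 rises of 15, with Tap1 at 1.83 (8.86e-11, and 0.0291 estimated), the list call that held at 18 h with an estimated correlation. Cytokines had 14 rises of 27 and 1 fall, Tgfb1 (6.79e-08, and adjusted p = 0.0624 estimated), chemokines 15 rises of 28 and 1 fall, Ccl6 (8.62e-07, and adjusted p = 0.0624), and maturation genes 12 rises of 24, with Cd86 at 2.27, and 1 fall, Cd44 (5.17e-07, and adjusted p = 0.121). NF-kB targets had 12 rises of 21 (3.51e-07, and adjusted p = 0.176), feedback genes 9 rises and 2 falls of 21 (0.00643, and adjusted p = 0.339) and the inflammasome list 4 rises of 13 (0.024, and adjusted p = 0.446). When adjusted over the list alone, 35 effectors, 9 GTPases, 0 ligands, 8 sensors, 4 IRF and STAT factors, 13 class I genes, 15 cytokines, 15 chemokines, 12 maturation genes, 13 NF-kB genes, 10 feedback genes and 4 inflammasome genes rose. Without control 18 h replicate 1 the calls of the sensor (adjusted p = 0.113), IRF and STAT (0.314) and inflammasome (0.314) lists were lost, and those of the inflammasome list without NCFM 18 h replicate 3 (0.0611) and of IRF and STAT factors without NCFM 18 h replicate 1 (0.0852); adjusted p over the alternatives reached 0.374, 0.425 and 0.446. Tlr3 (0.0947) and Ccl6 (0.151) were lost without control 18 h replicate 1, and Tgfb1 (0.0519) and Cd44 (0.0987) without control 18 h replicate 2, where the alternatives of Tgfb1 reached 0.0605.

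Enzymes of nitric oxide and prostanoid production rose at 18 h, with 12 rises of 22 (median 0.95, adjusted p = 6.79e-08, and 0.149 with an estimated correlation). They included Nos2 (3.71 ± 0.51), the prostaglandin E synthase Ptges (3.74 ± 0.62) and the heme oxygenase Hmox1 (3.24 ± 0.51). Glycolysis had 7 rises, including the glucose transporter Slc2a1 (1.08 ± 0.32) and the hexokinase Hk2 (1.18 ± 0.35), and 2 falls, Aldoc and Pfkfb4, of 23 (0.0153, and adjusted p = 0.446 estimated). Oxidative phosphorylation had 15 falls of 30 (median -0.55; 1.04e-04, and adjusted p = 0.374), cholesterol synthesis 14 of 20, including Sqle (-1.44) (median -0.86; 5.66e-07, and adjusted p = 0.175), and ribosomal proteins 10 of 18, including Rps6 (-1.48) and Rpl4 (-1.25) (median -0.71; 2.42e-06, and adjusted p = 0.339). A second probe set of Rps3 went the other way (0.24 against -0.61). The cell cycle list had a median of -1.07 with 3 falls, Cdk2, Mcm3 and Mcm7 (8.92e-04, and adjusted p = 0.633 estimated), and on it the number 1 arrays lie 1.00 higher. Without control 18 h replicate 1 the list lost its call, with a mean of -0.17. That fit also leaves 1 control array, numbered 2, so the number difference enters the comparison and that fit cannot tell whether the fall holds. The list kept its call and direction with the replicate number as a block. Without control 18 h replicate 1 the calls of Cdk2 (0.109), Mcm3 (0.262), Mcm7 (0.194), Hk2 (0.197) and Slc2a1 (0.0754) were lost too. Mcm3, Mcm7 and Hk2 were also lost without NCFM 18 h replicate 2 or 3, Slc2a1 without control 18 h replicate 2 (0.139, over a range of 0.0154 to 0.139) and Pfkfb4 without NCFM 18 h replicate 1 or control 18 h replicate 2 (up to 0.233). Adjusted over the list alone, 13 enzyme and 7 glycolysis genes rose, 15 oxidative phosphorylation, 15 cholesterol and 13 ribosomal genes fell, and no cell cycle gene passed. At 4 h the cell cycle list was not called (adjusted p = 0.366), but with the replicate number as a block it was (mean -0.31, adjusted p = 0.0317), as it was without NCFM 4 h replicate 1 (0.0189) or control 4 h replicate 3 (0.0394), over a range of 4.45e-04 to 0.989.

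**Figure D4:**
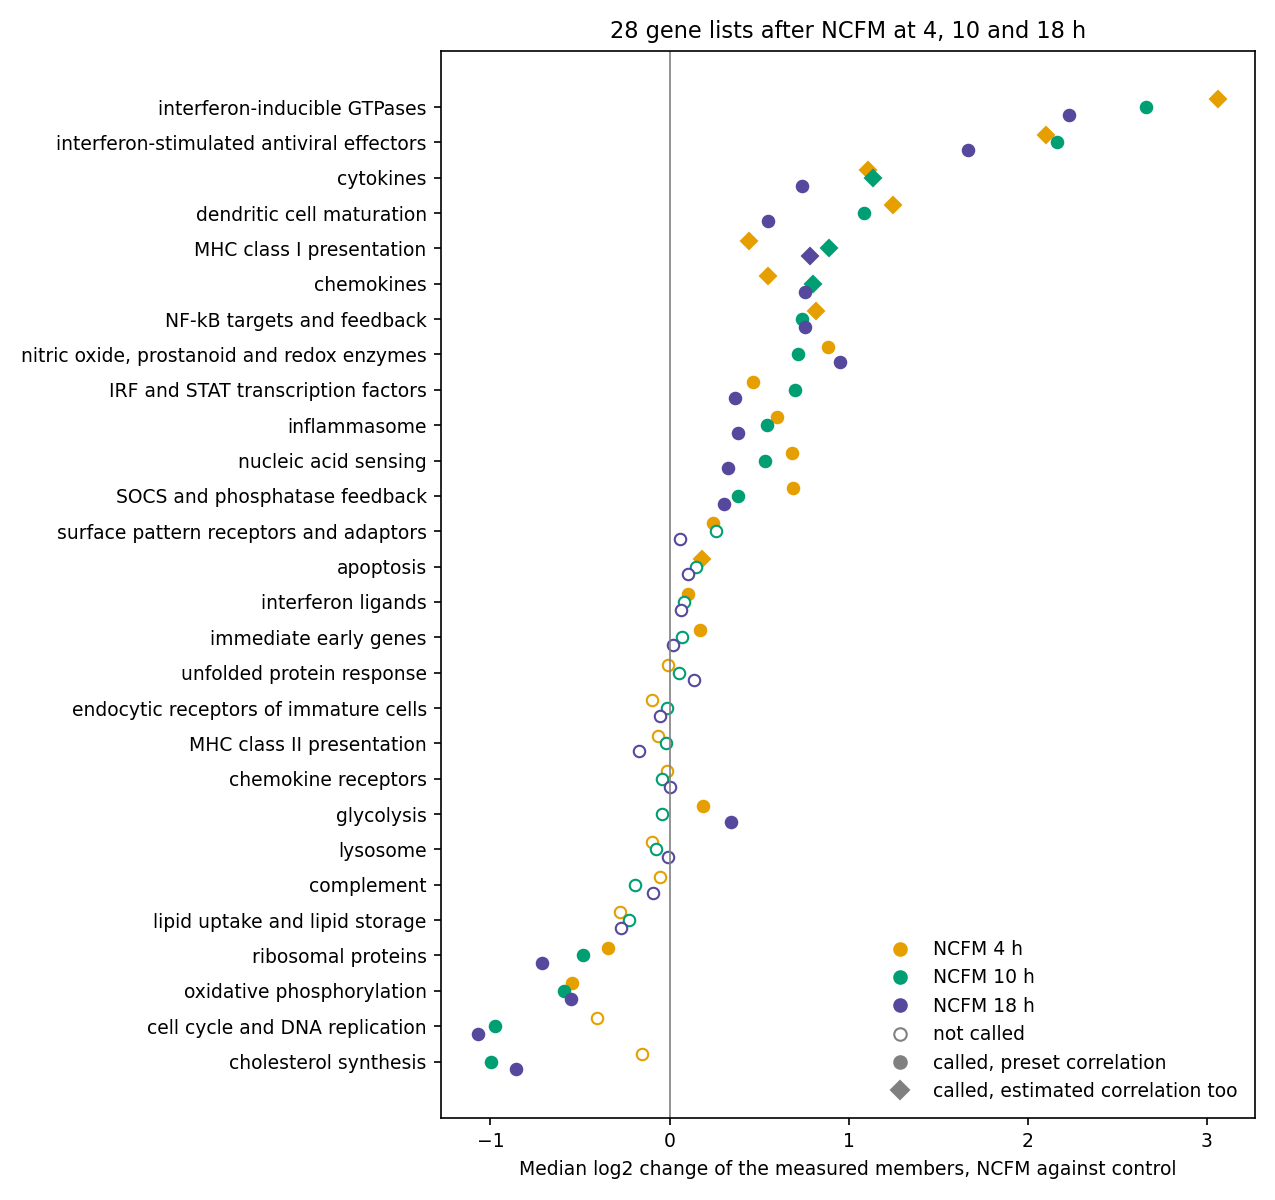
Median log2 change of the measured members of 28 gene lists, NCFM against control, at 4, 10 and 18 h (open points, not called; filled circles, called with the preset correlation; diamonds, called with an estimated correlation too). The antiviral effectors have medians of 2.10, 2.16 and 1.67, and cholesterol synthesis of -0.15, -0.997 and -0.86.

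Responses at the 3 times overlapped. Of the genes called, 438 were higher at all 3 times and 1229 lower, where independent lists would share 5.83 and 63.9. Opposite calls numbered 6 between 4 and 10 h, 48 between 4 and 18 h and 8 between 10 and 18 h. Across the 18193 genes, which are not independent replicates, the changes correlated at Pearson r = 0.827 (4 and 10 h), 0.874 (10 and 18 h) and 0.701 (4 and 18 h).

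Whether the response itself changes with time was tested as the difference of the NCFM effects. Between 4 and 10 h the heat shock genes Hspa1a (3.25 ± 0.46, adjusted p = 0.0152) and Hspa1b (2.63 ± 0.36) and Hamp, the gene of hepcidin (2.65 ± 0.37), gained, as did Cnn3 (2.59 ± 0.48), Rnf225 (1.91 ± 0.34) and Plat (1.81 ± 0.28). The effects on Ifnb1 (-2.13 ± 0.34), Mrc1 (-2.01 ± 0.25), Edn1 (-1.93 ± 0.25), Tfrc (-1.89 ± 0.27), Cited2 (-1.83 ± 0.32) and Emilin2 (-1.75 ± 0.30) moved down. In all 92 genes passed, 36 higher and 56 lower (60.9% lower, and 49.5% after quantile normalization). After spike-in centring 9119 passed, 42 higher and 9077 lower (99.5% lower), when the median difference of all genes was -0.43. With the replicate number as a block 457 genes passed, 175 higher and 282 lower. Between 10 and 18 h 1 gene passed, Asb13 (-1.04 ± 0.09, adjusted p = 0.00198), and 82 with the block. Asb13 lost its call with the mean of a gene's probe sets and with spike-in centring.

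Between 4 and 18 h the stress genes Ddit4 (3.19 ± 0.56, adjusted p = 0.0103), Ddit3 (2.53 ± 0.18) and Gadd45g (2.52 ± 0.41) gained, with Hamp (3.17 ± 0.37), Ankrd37 (2.58 ± 0.37) and H2-Q5 (2.77 ± 0.47). Ddit3 went from -0.48 at 4 h to 2.05 at 18 h. The effect on Tnf moved by -3.01 ± 0.27, from 4.62 to 1.61, and that on Ifnb1 by -2.66 ± 0.34, from 3.43 to 0.77. Mrc1 (-2.97 ± 0.25), Cebpd (-2.86 ± 0.30), Nfkbiz (-2.75 ± 0.47) and A630072M18Rik (-3.17 ± 0.56) also moved down. In all 619 genes passed, 216 higher and 403 lower (65.1% lower, and 54.2% after quantile normalization). After spike-in centring 773 passed, 71 higher and 702 lower (90.8% lower), when the median difference of all genes was -0.17. With the replicate number as a block 1665 passed, 587 higher and 1078 lower.

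Small groups of lists shifted between the times, each with the preset correlation only. Cholesterol synthesis moved down from 4 to 10 h (median -0.71, adjusted p = 6.07e-13, and 0.146 with an estimated correlation) and stayed lower at 18 h than at 4 h (-0.64; 1.47e-06, and adjusted p = 0.755 estimated). MHC class I presentation moved up from 4 to 10 h (0.33; 2.96e-05, and adjusted p = 0.146) and lay higher at 18 h than at 4 h (0.31; 0.0359, and adjusted p = 0.755). Neutrophil markers moved down from 4 to 10 h (-0.64; 0.0309, and adjusted p = 0.726). That call was lost without NCFM 4 h replicate 1 or 2, NCFM 10 h replicate 3, control 4 h replicate 3 or control 10 h replicate 2 (adjusted p up to 0.287). Its median ranged from -0.88 (without NCFM 4 h replicate 3) to -0.33 and -0.34 (without NCFM 4 h replicate 2 and NCFM 10 h replicate 3). The class I call from 4 to 18 h was lost without NCFM 4 h replicate 1, NCFM 18 h replicate 3, control 4 h replicate 1 or either control 18 h array (up to 0.0998), its median being 0.14 and 0.19 without NCFM 4 h replicate 1 and control 18 h replicate 1, and both cholesterol calls were kept without any single array (up to 2.24e-08 and 0.00517). Counts of genes between 4 and 10 h rest on single arrays: 12 genes passed without control 10 h replicate 1, when 11 of the 12 genes named for it lost their calls and Mrc1 kept its own (with background subtracted Mrc1 had -2.44 and lost it, adjusted p = 0.0904, over a range of 1.13e-06 to 0.0904), and 163 passed without control 10 h replicate 2. The other counts without an array were 16 and 19 (control 4 h replicates 2 and 3), 42 and 58 (NCFM 4 h replicates 2 and 3), 180, 24 and 29 (NCFM 10 h replicates 1, 2 and 3). Between 10 and 18 h they were 5 (NCFM 4 h replicate 3), 30 and 2 (NCFM 18 h replicates 1 and 3), 2 and 11 (control 10 h replicates 1 and 2) and 3 (control 18 h replicate 2), and between 4 and 18 h 302 and 364 (control 4 h replicates 2 and 3) and 312 (NCFM 18 h replicate 2).

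Control cells served as the measure of change with time in culture alone. No gene passed in limma between 4 and 10 h, 10 and 18 h or 4 and 18 h. Of the 18193 genes, 553, 653 and 559 had an unadjusted p under 0.05, fewer than the share of 0.05 that chance gives. With the replicate number as a block 880, 1088 and 1223 genes did. The lack of calls in the main fit therefore does not show that time in culture changes nothing. Genes passing with the block numbered 0, 2 and 1. Id3, an inhibitor of differentiation factors, lay lower at 18 h than at 4 h (-1.60 ± 0.09, adjusted p = 4.62e-05) and than at 10 h (-0.80 ± 0.10, adjusted p = 0.0449). Kdm2a, a histone demethylase, lay lower at 18 h than at 10 h (-0.88 ± 0.10, adjusted p = 0.0449). These genes were named after their values were seen. Without single arrays the counts between 4 and 10 h reached 3 (control 10 h replicate 2), those between 10 and 18 h 22 (control 18 h replicate 1), 2 (control 10 h replicate 2) and 1 (control 4 h replicate 3), and those between 4 and 18 h 33 (control 18 h replicate 1).

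Markers of 11 cell types were followed because bone marrow cultures hold several, and no list was called at any time. The lowest median was that of neutrophil markers, -0.35 at 4 h, -0.87 at 10 h and -0.81 at 18 h (adjusted p = 0.701, 0.134 and 0.257). Without NCFM 4 h replicate 3 the neutrophil median at 4 h was -0.06, and the lowest was then that of macrophage markers (-0.32, adjusted p = 0.616). At 10 h 5 of the 14 neutrophil genes fell, among them Ltf (-1.68), Mmp8 (-1.23) and Mmp9 (-1.36), and Lcn2 rose (1.25); at 18 h 4 fell and Lcn2 had 2.37. S100a8 and S100a9, the abundant neutrophil transcripts, had -1.04 and -1.12 at 10 h and did not pass. Macrophage markers went both ways, with Mrc1 lower and Fcgr1 (1.57), Marco (2.20) and Vcam1 (2.12) higher at 10 h (list medians -0.17, -0.01 and -0.10 at 4, 10 and 18 h; adjusted p = 0.574, 0.612 and 0.938). Dendritic cell markers had medians of -0.08, -0.29 and -0.29, with Clec10a and Itgax lower at 10 and 18 h (adjusted p = 0.701, 0.612 and 0.276). Without NCFM 4 h replicate 3 the neutrophil list was called at 10 h (adjusted p = 0.0412, over a range of 0.00705 to 0.74). When adjusted over the list alone, 7 neutrophil genes fell at 10 h and 4 at 18 h, and 2 dendritic cell genes fell at each of these times. Itgax and Marco lost their calls at 10 h without control 10 h replicate 1 or NCFM 10 h replicate 2 or 3. Mmp9 lost its call without control 10 h replicate 2, and Ltf without any of 7 arrays at 10 h and 11 at 18 h.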

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

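Tests on the share of another cell type, on the sex of the animals, on RNA quality, on the cell types of the number 1 arrays and on the animal behind number 3, and the list tests of differences between times, were chosen only after the result was seen. The response to NCFM differed between times for 92 genes (4 to 10 h), 1 gene (10 to 18 h) and 619 genes (4 to 18 h), by a test of the difference itself. Among genes the text names, it moved up from 4 to 10 h for Hspa1a (3.25), Hamp (2.65), Hspa1b (2.63), Cnn3 (2.59), Rnf225 (1.91), Plat (1.81), Ddit3 (1.77) and Asb13 (0.58). It moved down for Ifnb1 (-2.13), Mrc1 (-2.01), Edn1 (-1.93), Tfrc (-1.89), Cited2 (-1.83), Emilin2 (-1.75), Tnf (-1.71), Cebpd (-1.68), Gcsh (-1.55), Amz1 (-1.25), Fasn (-1.15), Srebf2 (-1.15), Gusb (-0.97) and Cfp (-0.87). From 10 to 18 h Asb13 moved by -1.04. From 4 to 18 h it moved up for Ddit4 (3.19), Hamp (3.17), H2-Q5 (2.77), Ankrd37 (2.58), Ddit3 (2.53), Gadd45g (2.52), Hspa1a (2.33), Lcn2 (2.15), Hspa1b (2.05), Ms4a4c (1.98), Isg20 (1.64), AI467606 (1.63), Rnf225 (1.51), Plat (1.40), Zfp36l2 (1.35) and Atf4 (0.74). It moved down over the same span for A630072M18Rik (-3.17), Tnf (-3.01), Mrc1 (-2.97), Cebpd (-2.86), Nfkbiz (-2.75), Ifnb1 (-2.66), Cited2 (-2.50), Edn1 (-2.39), Ccr2 (-2.34), Ccl4 (-2.00), Ch25h (-1.94), Clec4a2 (-1.71), Ap1s2 (-1.68), Ccl3 (-1.63) and Slc2a6 (-1.58). Smaller moves down were those of Mmp8 (-1.56), Gcsh (-1.44), Gusb (-1.41), Tfrc (-1.41), Cfp (-1.33), Rps6 (-1.19), Rpl4 (-1.18), Fasn (-1.10), Sting1 (-1.02), Vcam1 (-0.94), Herpud1 (-0.80) and Asb13 (-0.47).

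Gene lists whose response differed between times, by camera at the preset correlation, are given as median differences. From 4 to 10 h these were MHC class I presentation (0.33), cholesterol synthesis (-0.71) and neutrophil markers (-0.64). From 10 to 18 h they were antiviral effectors (-0.32, adjusted p = 0.00447), maturation genes (-0.36, 0.0465), glycolysis (0.29, 0.00447) and ribosomal proteins (-0.32, 0.00607), all with adjusted p = 0.899 under an estimated correlation. From 4 to 18 h they were antiviral effectors (-0.41, 0.0451), sensors (-0.43, 0.0451), cytokines (-0.38, 0.0134), MHC class I presentation (0.31), cell cycle (-0.64, 0.0134), cholesterol synthesis (-0.64) and ribosomal proteins (-0.42, 0.00124), all with adjusted p = 0.755 under an estimated correlation. Most of these calls rest on single arrays. Those from 10 to 18 h were lost without any of 3 arrays (antiviral effectors: NCFM 10 h replicate 3, control 10 h replicate 1 and control 18 h replicate 2; adjusted p up to 0.823), 8 (maturation: NCFM 4 h replicate 2, NCFM 10 h replicates 1 and 3, NCFM 18 h replicates 2 and 3, control 4 h, 10 h and 18 h replicates 2; up to 0.396), 1 (glycolysis: NCFM 10 h replicate 1, 0.09) and 3 (ribosomal proteins: NCFM 10 h replicate 1, NCFM 18 h replicate 3 and control 10 h replicate 2; up to 0.142). Those from 4 to 18 h were lost without any of 8 arrays (antiviral effectors: NCFM 4 h replicates 2 and 3, NCFM 18 h replicate 1, control 4 h replicates 1 and 3, control 10 h replicates 1 and 2 and control 18 h replicate 2; up to 0.606), 7 (sensors: the same arrays but control 4 h replicate 3; up to 0.496), 4 (cytokines: NCFM 4 h replicate 2, NCFM 18 h replicate 3, control 4 h replicate 1 and control 18 h replicate 2; up to 0.0877) and 4 (cell cycle: NCFM 4 h replicate 1, control 4 h replicates 2 and 3 and control 18 h replicate 1; up to 0.409). Directions turned as well, where leaving out 1 control array also changes the share of number 1 arrays in its group. From 10 to 18 h the antiviral effector median was 0.06 without control 10 h replicate 1 and 0.13 without control 18 h replicate 2, against -0.66 and -0.77 without control 10 h replicate 2 and control 18 h replicate 1. From 4 to 18 h it was 0.16 without control 18 h replicate 2 and -0.80 without control 18 h replicate 1, and the sensor median -0.08 and -0.66 without these arrays and -0.24 without NCFM 4 h replicate 3. The cell cycle median was 0.09 without control 18 h replicate 1 and -1.44 without control 18 h replicate 2, -1.12, -0.39 and -0.43 without control 4 h replicates 1, 2 and 3, and -0.32 without NCFM 4 h replicate 1. Other medians that moved by over 1.5 times were those of cytokines (-0.21 without control 4 h replicate 1), maturation genes (-0.56 without control 18 h replicate 1), glycolysis (0.14 without control 10 h replicate 2, 10 to 18 h) and ribosomal proteins from 10 to 18 h (-0.19 without NCFM 10 h replicate 1 or NCFM 18 h replicate 3). The ribosomal call from 4 to 18 h was kept without any single array (up to 0.0276). Without NCFM 4 h replicate 3 further lists were called from 4 to 10 h, namely cytokines (-0.23, 0.0328), cell cycle (-0.59, 0.00321), oxidative phosphorylation (-0.29, 9.35e-06) and ribosomal proteins (-0.34, 9.35e-06). From 4 to 18 h these were nitric oxide and prostanoid enzymes (0.37, 0.0294), oxidative phosphorylation (-0.28, 0.00312), dendritic cell markers (-0.39, 0.0488) and neutrophil markers (-0.80, 0.0107). Among the 10092 probe sets that name no single gene, which the comparisons leave out, 706 (356 higher, 350 lower), 977 (510 higher, 467 lower) and 851 (405 higher, 446 lower) were called against control at 4, 10 and 18 h.

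More genes fell than rose at each time: 71.2, 66.7 and 68.8% of the calls were falls. The authors' scaling stays open, since the lowest share of falls over quantile normalization and median centring was 50%, the bound set beforehand for it. Centring on the spike-in probe sets turned the split at 4 h (17.8% falls), while at 10 and 18 h it gave 90.2 and 71.5%. It was applied to values already normalized by the authors. The spike-in mean (log2) was 11.25 ± 0.13 (SD, n = 9) with NCFM and 11.25 ± 0.11 (n = 7) in controls. At 4 h it was 11.02 to 11.23 with NCFM against 11.25 to 11.45, and at 10 h 11.31 to 11.51 against 11.12 to 11.16. These splits thus follow spike-in differences between few arrays and do not show the direction of the response. The upper quartile of the arrays was 343 ± 6.91 (SD, n = 9) with NCFM and 380.3 ± 8.08 (n = 7) in controls. Loss of another cell type stays open at all 3 times. The lowest list median was that of neutrophil markers, -0.35, -0.87 and -0.81 at 4, 10 and 18 h (SD of the 14 genes 0.46, 0.79 and 1.07), and the genes called lower had medians of -0.53, -0.66 and -0.67. The differences are within the spread of the markers, the genes they are set against were chosen for being lower, and no such list was called. The 4 h median was -0.06 without NCFM 4 h replicate 3. A response of the cells to NCFM, the biological explanation of the design, remains open as well. For the count at 4 h the 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 3335 genes and the others at most 0, among them the other 3 that part all pairs of numbers, so 1 split gave as many. Each other split mixes NCFM and control arrays in its groups, which puts the difference between treatments into the spread. Their lack of calls therefore says little about chance.

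The number 1 arrays deviated together in all 6 groups, with 3286 of 18193 genes (18.1%, where chance gives 3.13%) on a single side in all of them and 161 of these at 1 log2 unit or more. In 6 of 6 groups the number 1 array had the lowest Xist and the highest Eif2s3y, Kdm5d and Uty, which is consistent with animals of the other sex. Sex-linked genes alone are argued against, since without X and Y the lowest correlation between number 1 arrays was 0.34. A difference in RNA quality or 3' bias stays open: the number 1 array had the lowest 3' to 5' ratio in 4 of 6 groups, where chance gives 2.33. A different share of another cell type stays open, with macrophage markers differing by -0.50. Apoe (-3.72) and F13a1 (-2.33) were among the single genes of 1 sign. The Xist and Y-linked values show that the number 1 arrays came from other animals than their partners. Whether a difference between animals or cultures, which the design does not name, accounts for the rest of the deviation stays open and was not tested.

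NCFM 4 h replicate 3 lay apart from its partners, with 321 brighter genes at least 2-fold lower. Loss of short transcripts may account for part of it: genes spanning at most 1000 bases, without the oxidative phosphorylation and ribosomal lists, lay lower than the other genes (difference of medians -0.49; 44 of 60 lower), among them S100a8 (-2.93, 964 bases). Genes with longer spans fell as far, such as Romo1 (-2.86, 1642 bases), Ndufa3 (-2.81, 2819 bases) and Son (-2.67, 31369 bases), and the span of a gene is not the length of its transcript. S100a8 is also a neutrophil marker, as is S100a9 (-2.84, 3092 bases). The median of the neutrophil markers at 4 h was -0.35, and -0.06 without this array. A different share of cells on this array was not tested. The animal behind number 3 stays open: the lowest correlation with the other number 3 arrays was 0.36 (0.48, 0.36 and 0.45 across genes), within the 0.19 to 0.75 of all same-number pairs. On the other number 3 arrays 30, 65 and 22 brighter genes lay at least 2-fold lower (NCFM 10 h, NCFM 18 h and control 4 h). The design gives no biological explanation for a single array, and none was tested.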

How the results depend on the processing

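Tests with only arrays 2 and 3, only arrays 1 and 2 with the block, background subtraction and spike-in centring were chosen only after the result was seen. Named genes gave 12247 values under 30 alternatives (409 results): 11597 kept their side of the threshold, 513 lost a call, 137 gained a call and 0 reversed. Direction was compared only where the main fit or the alternative called the result. Lists gave 3744 values under 32, and by the same rule 3621 kept their side of the threshold. A call was lost by 79 (40 with the estimated correlation and 7 with fry) and gained by 43 (13 with fry). Fry tests a list against no change, so its 7 and 13 are not changes of the camera call. The 1 reversal was the cell cycle list at 10 h without control 10 h replicate 1 (mean -0.12, and -1.53 without control 10 h replicate 2). Each of these 2 fits leaves a single control array, so the difference between array numbers on this list enters the comparison. Camera with the estimated correlation called 8, 3 and 1 pathway lists at 4, 10 and 18 h, where the preset called 19, 16 and 17. Gene counts moved by over 1.5 times as follows, and the cause was not tested where it is not named. NCFM counts at 4, 10 and 18 h were 5815, 8186 and 7730 with all probe sets (more features tested), 582, 1127 and 1097 with a change of at least 1 log2 unit, and 1713, 2585 and 2416 at adjusted p under 0.01 (stricter by construction); array weights gave 5671 at 4 h, and only the groups compared 2449 at 18 h (fewer samples). Counts for the difference between 4 and 10 h (92) were 457 with the replicate block, 419 with array weights, 55 with the trend and robust variance, 42 and 7 with the stricter thresholds, 309 with arrays 2 and 3, 22 with arrays 1 and 2, and 9119 with spike-in centring. For 10 to 18 h (1) they were 82 with the block, 17 with all probe sets, 0 with the mean of probe sets, 33 with arrays 2 and 3, 12 with arrays 1 and 2, 2 with background subtracted and 4 with spike-in centring. For 4 to 18 h (619) they were 1665 with the block, 951 with all probe sets, 1129 with array weights, 265 and 160 with the stricter thresholds and 1593 with arrays 2 and 3. In control cells (0) the counts from 10 to 18 h were 2 with the block and 1 with background subtracted, and from 4 to 18 h 1 each with the block, dim genes left out, trend and robust variance, array weights, arrays 1 and 2, and background subtracted, and 100 with arrays 2 and 3 (this leaves 1 array each in the 10 and 18 h controls, assumed to vary like the other groups). Cell type lists (0) were 1 with the mean of probe sets, 3 with all probe sets, 1 with only the groups compared and 1 with arrays 1 and 2. The block also called the cell cycle list at 4 h; of the named genes 22 values gained a call (at 4 h Cdk2, Fasn, Fcgr4, Gla, Hk2, Hmox1, Il10, Klf2, Ltf, Man2b1, Marco, Mcm7, Nos2, Ptges, Tlr1, Tlr2 and Trem2; at 10 h Cd44, Hk2, Mcm3 and Mcm7; at 18 h Gmnn), and Ifna4 lost its call at 10 h. In control cells it called Id3 (4 to 18 and 10 to 18 h) and Kdm2a (10 to 18 h). Among the other named genes, and the lists against control at the 3 times, it changed no other call; list differences between times were not run with it. Of 301 called NCFM values of named genes 87 lost the call without at least 1 array. After spike-in centring the median change of all genes was 0.18, -0.24 and 0.02 at 4, 10 and 18 h (-0.0066, 0.0083 and 0.0022 as deposited), and -0.43, 0.25 and -0.17 for the differences 4 to 10, 10 to 18 and 4 to 18 h. The share of falls at 4, 10 and 18 h was then 17.8, 90.2 and 71.5%, and 70.9, 65.3 and 70.9% with median centring. Lists called at a time kept the sign of their mean under these scalings. Without single arrays the counts ranged from 2138 to 3653, 2134 to 4755 and 2868 to 4503 at 4, 10 and 18 h, from 12 to 180 (4 to 10 h), 1 to 30 (10 to 18 h) and 302 to 791 (4 to 18 h), in control cells from 0 to 3, 0 to 22 and 0 to 33 (4 to 10, 10 to 18 and 4 to 18 h), for lists from 17 to 20, 16 to 18 and 13 to 17, and for cell types from 0 to 1. Signal over background limits dim genes: the array medians were 162 to 167 and the 5th percentiles 65 to 67. Ptgs2 in controls and Mrc1 with NCFM at 18 h lay lower than the array medians, and so did Il10 and Ifna4 in controls at 10 h (3.05 and 0.27, and 4.32 and 0.60 with background subtracted) and Ccr9 with NCFM at 18 h.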

Other observations

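The gene lists and tests in this part were fixed before the data were examined, and the genes named from them were picked after their values were seen. Several lists moved in both directions and were not called as a whole. Among 23 endocytic receptors of immature cells, the mannose receptor Mrc1 (-3.58 ± 0.18 at 18 h, SE, n = 3 against 2), Clec4a2 and Clec10a (-2.44 ± 0.35) fell, while the Fc receptors Fcgr4 (2.49) and Fcgr1 (1.40), the scavenger receptor Marco (2.06) and Ly75 (0.88) rose (list adjusted p = 0.882, 0.913 and 0.924 at 4, 10 and 18 h). Adjusted over the list alone, 2, 5 and 4 rose and 4, 4 and 3 fell at these times. Of 13 chemokine receptors Ccrl2 rose at all 3 times (3.31, 3.02 and 2.56) and Ccr2 fell, Cxcr4 fell at 4 h, Ccr9 fell at 18 h and Cxcr5 rose at 10 and 18 h (0.918, 0.843 and 0.956; adjusted over the list alone 1, 2 and 2 rises and 2, 2 and 2 falls). Complement had Cfb, an enzyme of the alternative pathway, higher (2.12, 3.33 and 3.43) and Cfp, properdin, lower (-0.28, -1.14 and -1.60), with Serping1 higher at 10 and 18 h and Cr1l lower at 18 h (0.892, 0.913 and 0.574; adjusted over the list alone 1, 2 and 2 rises and 0, 1 and 3 falls). MHC class II genes hardly passed: H2-DMa, which loads peptides, fell (-0.63, -1.38 and -1.53), and Cd74 and Ciita fell at 18 h (-0.23 and -0.54; list 0.882, 0.529 and 0.133; adjusted over the list alone 1, 1 and 3 falls). On the number 1 arrays the complement list lay lower (mean difference -0.76), as did the lysosome list (-0.34). Several calls of genes here were lost when a single array was left out. Leaving out an 18 h control array also changes the share of number 1 arrays in its group. With the replicate number as a block all of the calls listed below were kept. Without control 18 h replicate 1 those of Fcgr4, Marco, Cxcr5, Serping1, Cd74 and Ciita at 18 h were lost. Without control 18 h replicate 2 those of Ccr9, Cr1l, Marco, Cxcr5, Serping1 and Cd74 were lost. The 18 h call of Ciita was lost without any of 10 arrays. Those of Marco, Serping1 and Cd74 were lost without any of 4, and those of Fcgr4, Cxcr5, Ccr9 and Cr1l without any of 3. At 10 h that of Cxcr5 was lost without control 10 h replicate 2, and its adjusted p ranged from 0.00207 to 0.0945 over the alternatives. At 4 h that of Cfp was lost without any of 12 arrays (adjusted p up to 0.141), that of Cfb without NCFM 4 h replicate 2 or 3 or control 4 h replicate 1 (up to 0.0621), and that of H2-DMa without NCFM 4 h replicate 3 or control 4 h replicate 2 (up to 0.0663, and up to 0.0892 over all alternatives).

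Lipid and organelle lists were mixed too. Lipid uptake and storage genes had 3, 5 and 4 falls of 18 at 4, 10 and 18 h, among them Fasn (-1.48 at 10 h), Pparg (-0.90) and Scd2 (-2.29), while Ch25h rose at each time (4.58, 4.42 and 2.64; list 0.333, 0.392 and 0.237; adjusted over the list alone 3, 6 and 5 falls). Lysosomal genes had Gusb (-1.98 ± 0.12 at 18 h), Man2b1 (-1.50) and Atp6v0d2 (-1.26) lower and Gla (1.42) and Ctsk (0.99) higher (0.409, 0.801 and 0.841; adjusted over the list alone 0, 3 and 2 rises and 2, 5 and 4 falls). Without NCFM 4 h replicate 3 that list was called at 4 h (adjusted p = 0.0499, over a range of 0.0172 to 0.945). In the unfolded protein response Herpud1 fell (-0.70, -1.39 and -1.49) and Ddit3 went from -0.48 to 2.05, with Atf4 (0.62) and Trib3 (0.66) higher at 18 h (0.918, 0.803 and 0.276; adjusted over the list alone 0, 1 and 5 rises and 2, 1 and 4 falls). Cholesterol synthesis was not called at 4 h (median -0.15, adjusted p = 0.366), when Dhcr7, Ebp and Mvd fell (adjusted over the list alone 3). Without NCFM 4 h replicate 3 its median was -0.26, with 4 falls, and still not called (adjusted p = 0.0606, over a range of 0.0606 to 0.981). Glycolysis was not called at 10 h (0.913), with 3 rises, including Hk3 (1.71), and 5 falls, including Aldoc (-1.49); adjusted over the list alone there were 5 rises and 5 falls. Apoptosis genes were not called at 10 h (0.0663) or 18 h (0.147), with Mlkl at 2.26 and 2.39 and Ripk3 at -0.82 and -0.58; adjusted over the list alone there were 5 and 4 rises and 2 and 2 falls. At 10 h that list was called without NCFM 4 h replicate 3 (0.0473), NCFM 10 h replicate 2 (0.0369) or control 10 h replicate 1 (0.00808), over a range of 0.000944 to 0.275. Immediate early genes (0.71 and 0.471 at 10 and 18 h) had Junb (0.83 and 1.09) and Atf3 (1.48 and 1.92) higher and Klf2 (-1.17 and -1.10) lower, with 5 and 4 rises and 6 and 2 falls adjusted over the list alone. Surface pattern receptors (0.529 and 0.596) had Tlr1 (2.22 and 1.97) and Clec4e (1.79 and 2.04) higher and Trem2 (-1.34 and -1.56) lower, with 7 and 4 rises and 6 and 4 falls adjusted over the list alone. Without the number 1 control array of the same time the calls of Tlr1 and Clec4e at 10 and 18 h, Gla and Ctsk at both, Atf3 and Junb at 10 h and Ripk3 at 18 h were lost. The calls of Tlr1 at both times, Clec4e at 10 h and Ripk3 at 18 h were also lost without NCFM replicate 2 or 3 of that time. The calls of Trem2 at 10 and 18 h, and of Atf4 and Trib3 at 18 h, were lost without the control array numbered 2. That of Mvd at 4 h was lost without any of 6 arrays (adjusted p up to 0.143). With the replicate number as a block none of these calls was lost.

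The remaining 8 cell type lists were not called at 4, 10 or 18 h. Their medians were 0.02, 0.02 and -0.02 for mast cells and basophils (adjusted p = 0.574, 0.559 and 0.731), 0.16, -0.18 and -0.33 for eosinophils (0.589, 0.861 and 0.731), and -0.01, 0.04 and 0.03 for B cells (0.701, 0.612 and 0.731). They were 0.06, 0.07 and 0.12 for T and NK cells (0.574, 0.612 and 0.276), -0.01, 0.16 and 0.01 for plasmacytoid dendritic cells (0.602, 0.443 and 0.731), and 0.07, -0.0038 and -0.02 for erythroid cells and megakaryocytes (0.574, 0.612 and 0.731). They were 0.03, -0.01 and -0.12 for stem and progenitor cells (0.701, 0.861 and 0.731), and 0.06, 0.09 and 0.11 for stromal cells (0.463, 0.248 and 0.257). Single genes in them passed, such as Hdc, the histamine-forming enzyme (1.08, 1.56 and 1.15), Ighm (-1.14, -1.05 and -1.37) and Kdr (1.29, 2.23 and 1.84). Ighm lost its call at 10 h without control 10 h replicate 2 (adjusted p = 0.0625), and at all 3 times with the mean of its 11 probe sets (-0.18, -0.15 and -0.28, adjusted p = 0.188, 0.3 and 0.0636). Its adjusted p ranged down to 8.07e-05, 3.14e-04 and 5.93e-05. Kdr lost its call at 4 h without NCFM 4 h replicate 2 or 3 or control 4 h replicate 2 or 3 (up to 0.0591).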
